A study of Drosophila melanogaster with 4 samples.

How the data were processed

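Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an antibody against dimethylated lysine 36 of histone H3 (H3K36me2) on head nuclei of adult wild-type Drosophila melanogaster of the Oregon-R strain. The labels define 4 samples, namely 2 ChIP samples and 2 input DNA samples, and each input label names the ChIP region list for which it served as the background. Per the labels' protocols, heads were collected with sieves, the tissue was fixed with formaldehyde, chromatin was sheared by sonication, and antibody-bound chromatin was recovered on protein A beads. The labels do not say whether the replicates came from separate fly collections, so differences between them measure only the spread between these samples, which may be technical.

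The authors deposited 3 lists of regions, 1 for each ChIP replicate and 1 for the replicate set. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers, which also give the lengths of 14 sequences. These are the 5 large chromosome arms (2L, 2R, 3L, 3R and X), the 4th chromosome, 6 sequences of assembled heterochromatin (named Het) and the unplaced collections U and Uextra. The region caller, its threshold, its minimum region length and the way in which the replicates were combined are not given in the sources used here. Each region carries a score that the authors deposited with no stated scale. The score was below 0 only in regions that the lists name as depleted, and it was used to describe, rank, filter and compare regions within a list. Between lists it was used for the correlation of the replicates across paired regions, and beside named regions. The lists give no read counts, so sequencing depth is unknown, no interval for read sampling can be given, and the precision of region boundaries rests on the comparison of the replicates.

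Regions named as enriched were analysed, and the few named as depleted were kept apart. No enriched region overlapped another in the same list, so the covered length was the sum of region lengths. The covered share of a sequence was that sum divided by the sequence length in the file headers, in which unsequenced or unalignable bases were not separated. Values over replicates are the mean ± SD of the 2 ChIP lists. A region was called shared when at least 1 bp overlapped a region of the other list, and shares of regions are given with Wilson 95% intervals, which cover counting error only. The overlap of the replicate lists was summarised by the Jaccard index, the covered length in common divided by the length covered in either. It was tested by rotating the replicate 2 list by a random distance around each sequence in bins of 100 bp, with 100000 rotations and a two-sided permutation p. The computation was checked on lists made from the 6161 regions of the replicate 1 list, with 1000 rotations for each. Of 100 copies of that list rotated at random along each sequence, 2% gave a p under 0.05. Of 100 lists that kept about 50% of the regions with unchanged boundaries, 100% did. Both outcomes were nearly fixed by how the lists were made, so they do not show whether rotation is a fair null. The exact Jaccard index was also checked against bedtools 2.31.1. Score agreement was computed across regions that overlapped one-to-one, and regions are not independent replicates. Covered shares were also computed in windows of 500 kb. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

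Except where the text says that they were chosen after seeing the data or the results, the tests, the alternatives and the rule for named regions were fixed before the data were examined. Under that rule the text names the 5 longest and the 5 highest-scoring regions of the replicate-set list, the longest region of each sequence, and the 5 longest regions of 1 replicate without overlap in the other. Any region or window named outside the rule is identified as chosen after its values were seen. The alternatives were joining regions closer than 1 kb, keeping the higher-scoring 50% of each list, requiring 50% of a region's length to overlap, restricting the overlap to the 5 large arms, bins of 1000 bp, measuring each sequence from its first to its last region, using the replicate-set list, and leaving out each replicate.

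The 3 planned comparisons with gene annotation (genomic features, position along genes and 15 gene lists) were not run. The gene table used here describes release 6 of the genome, and release 5 coordinates were not converted. No gene is therefore named. Inputs entered only through the authors' lists, since no input values were analysed here. With 2 replicates no permutation of samples can give a p under 0.05, so differences between chromosome arms are set against the spread between replicates without a test.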

Results

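Dimethylation of lysine 36 of histone H3 (H3K36me2) is a modification associated with transcribed chromatin. Its distribution was mapped in adult Drosophila heads, a tissue rich in neurons and photoreceptors, by ChIP-seq in 2 ChIP samples, each paired by its label with an input sample. The authors' lists held 6161 enriched regions in replicate 1, 6078 in replicate 2 and 6411 in the replicate set. Read depth is unknown, because the lists give regions and scores but no counts.

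Enriched regions covered 31.5 Mb in replicate 1, 31.6 Mb in replicate 2 and 35.0 Mb in the replicate-set list. On the 5 large chromosome arms this was 24.5% ± 0.018 (SD, n = 2) of the sequence in the replicates and 27.2% in the replicate-set list. The regions were broad. Their median length was 3624 bp in replicate 1 and 3679 bp in replicate 2, with the middle 90% between 1494 and 13476 bp and between 1506 and 13754 bp, respectively. Regions of 10 kb or longer numbered 640 in replicate 1 and 662 in replicate 2, and they held 32.2% ± 0.47 (SD, n = 2) of the covered length. Longer regions carried higher scores, with a Spearman rho across regions of 0.80 in each replicate. The shortest region was 1301 bp in both replicates and 1001 bp in the replicate-set list, so shorter patches of the mark are not represented.

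The first comparison asked whether the 2 ChIP replicates marked the same regions. The same parts of the genome were enriched in both. Of the replicate 1 regions, 5883 of 6161 overlapped a replicate 2 region, or 95.5% (Wilson 95% interval 94.9 to 96.0%). Of the replicate 2 regions, 5783 of 6078 overlapped a replicate 1 region, or 95.1% (94.6 to 95.7%). The Jaccard index of the covered length was 0.903, against a mean of 0.142 and a maximum of 0.257 when the replicate 2 list was rotated along each sequence. The two-sided permutation p by rotation was 1e-05, the smallest that 100000 rotations can give. Lists of the same mark from the same tissue were likely to overlap more than rotated ones. The p therefore speaks only against unrelated placement and adds little to the index. The index lay between 0.909 and 0.915 on the 4 large autosomal arms. It was 0.867 on X, 0.897 on the 4th chromosome and 0.802 on the unplaced sequence U. No region had identical start and end positions in the replicate lists, and starts and ends of regions paired one-to-one differed by a median of 89 and 88 bp.

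Regions that overlapped nothing in the other replicate were mostly short and low in score, with 97.1% of them in replicate 1 and 93.9% in replicate 2 under the median score of their list. The 278 such regions of replicate 1 had a median length of 1583 bp and a median score of 0.542, against 3789 bp and 1.03 for its shared regions. The 295 of replicate 2 had a median length of 1587 bp and a median score of 0.487, against 3856 bp and 1.02. An exception, chosen after its value was seen, was 2RHet 1534827 to 1536174, whose score of 3.50 was the highest in replicate 2. The longest of them in replicate 1 was a 3.83 kb region of 3R (20312528 to 20316355) with a score of 0.803. It was followed in replicate 1 by X 3802133 to 3805755 at 3.62 kb, 3R 13690265 to 13693581 at 3.32 kb and X 21107086 to 21110311 at 3.23 kb. The longest in replicate 2 was X 9050642 to 9054073 at 3.43 kb. Each of these 5 regions overlapped a region of the replicate-set list over at least 94.8% of its length.

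Region scores were also similar in the replicates. Across the 4898 regions paired one-to-one, scores in the replicates had a Pearson r of 0.971 and a Spearman rho of 0.964. Their lengths had a Pearson r of 0.994. These correlations are across regions, which are not independent replicates, and pairing leaves out regions that 1 list splits.

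**Figure D1:**
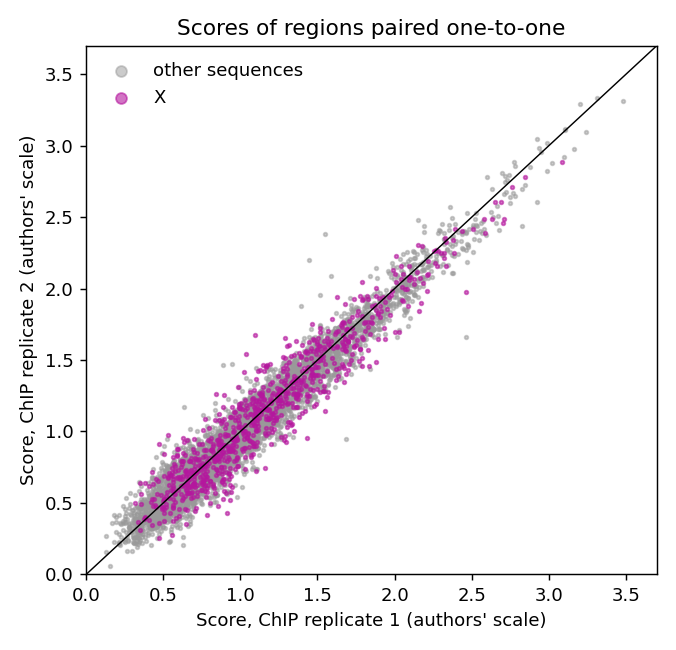
Score of each of the 4898 enriched regions paired one-to-one, in ChIP replicate 1 (x axis) and ChIP replicate 2 (y axis), on the authors' scale; each point is a region, regions on X are coloured, and the line marks equal scores. The points lie along the line of equal scores with a Pearson r of 0.971.

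The replicate-set list contained nearly all of both replicate lists. It overlapped 99.9% of the regions of replicate 1 and 99.9% of those of replicate 2, which left 9 and 6 regions outside it. Of its 6411 regions, 5225 overlapped both replicates, and these made up 94.6% of its covered length. A further 242 overlapped only replicate 1, 270 overlapped only replicate 2 and 674 overlapped neither. Those found in neither were short, with a median of 1287 bp, and had a median score of 0.351, against 4621 bp and 1.00 for those found in both. How the authors combined the replicates is not given in the sources used here.

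The second comparison was between chromosome arms. The 4th chromosome, a small chromosome in which genes lie within heterochromatin-like sequence, had the highest covered share of any sequence. Regions covered 53.1% ± 1.9 (SD, n = 2) of it, 2.13 ± 0.088 (SD, n = 2) times the share of the 4 large autosomal arms, which was 24.9% ± 0.15 (SD, n = 2). The ratio was 2.07 in replicate 1 and 2.19 in replicate 2, a spread far smaller than the difference from 1. Regions on the 4th chromosome were not higher in score, with a median of 0.900 in replicate 1 and 0.922 in replicate 2 against 0.951 to 0.984 on the large autosomal arms. Their median length was 4051 bp in replicate 1 and 4338 bp in replicate 2, against 3642 to 3847 bp on those arms. In the replicate-set list it was shorter than on those arms, 3818 bp against 3859 to 4034 bp. The median score there was 0.710, against 0.843 to 0.858 on those arms.

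Among the large autosomal arms 2R had the largest covered share, 28.9% ± 0.20 (SD, n = 2). It was followed by 3R at 25.3% ± 0.25, 3L at 23.4% ± 0.087 and 2L at 22.5% ± 0.060. The gaps between these arms exceeded the replicate SD in each case. X, the chromosome whose transcription is raised in males by dosage compensation, was covered over 22.5% in replicate 1 and 23.2% in replicate 2. Its ratio to the autosomal arms was 0.916 ± 0.028 (SD, n = 2), below 1 in both replicates. In replicate 1 its share was slightly below that of 2L, the least covered autosomal arm, and in replicate 2 it was above that of 2L, which was 22.5%. The sex of the flies was not used here, and no link between these values and dosage compensation was tested.

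Regions on X were shorter and higher in score than those on the autosomal arms. Their median length was 3208 bp in replicate 1 and 3468 bp in replicate 2. Their median score was 1.07 in replicate 1 against 0.978 for the autosomal arms together, and 1.08 in replicate 2 against 0.968. In the replicate-set list the medians were closer, 0.874 on X and 0.853 on the autosomal arms.

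The assembled heterochromatin was covered over a smaller share of its length than the autosomal arms. The 5 heterochromatin sequences with regions were covered over 15.7% ± 0.20 (SD, n = 2), 0.629 ± 0.012 (SD, n = 2) times the autosomal share. The ratio was 0.713 when each sequence was measured from its first to its last region. Unsequenced or unalignable bases were not separated from the lengths, so a lower level of the mark does not follow. Shares ranged from 7.31% ± 0.061 on 3RHet to 19.0% ± 0.27 on 2RHet and 20.6% ± 0.20 on 3LHet. Median scores were not lower throughout. They were 1.69 in replicate 1 and 1.52 in replicate 2 on 2LHet (8 and 6 regions), 1.19 and 1.39 on 2RHet (88 and 83 regions), and 1.30 and 1.44 on 3RHet (20 and 18 regions), above the medians of all 5 large arms. On 3LHet they were 0.969 and 1.04, and on XHet 0.811 and 0.746. No region was listed on YHet, which has 347 kb, or on Uextra, which has 29.0 Mb, and U had a covered share of 2.04% ± 0.14 (SD, n = 2). The lists do not show whether these sequences lacked the mark or lacked reads that could be placed.

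**Figure D2:**
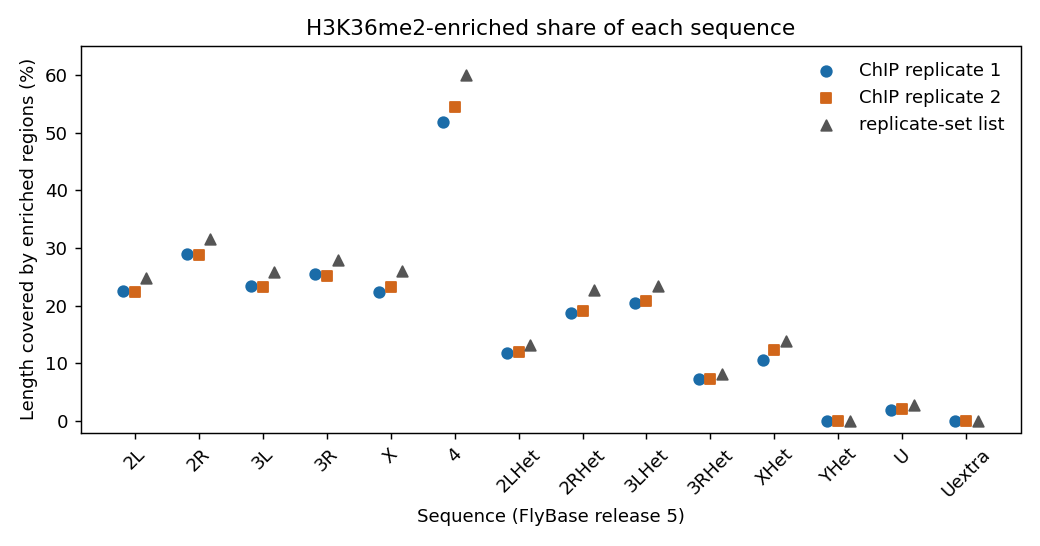
Share of each sequence's length covered by enriched regions (y axis, percent) for the 14 sequences named in the file headers (x axis); circles are ChIP replicate 1, squares ChIP replicate 2 and triangles the replicate-set list. The 4th chromosome lies at 51.8% in replicate 1 and 54.4% in replicate 2, above every other sequence, and YHet and Uextra have no region.

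Within the arms enrichment was uneven over long distances, and the unevenness was shared between replicates. In 236 windows of 500 kb on the 5 large arms the mean covered share ranged from 2.11 to 54.3%, with a median of 24.1%. The replicates never differed by more than 3.91 percentage points in a window, and across windows Pearson's r was 0.996. The windows named here were chosen after their values were seen. The most covered window was 3R 1000001 to 1500000 with 54.3% ± 0.62 (SD, n = 2). It was followed by 3L 1500001 to 2000000 with 49.9% ± 0.81, 2L 8000001 to 8500000 with 49.8% ± 0.42 and 2R 1000001 to 1500000 with 49.4% ± 0.23. The least covered were 2R 15500001 to 16000000 with 2.11% ± 0.056, 2L 14500001 to 15000000 with 2.17% ± 0.025 and 3L 18000001 to 18500000 with 4.27% ± 0.48.

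**Figure D3:**
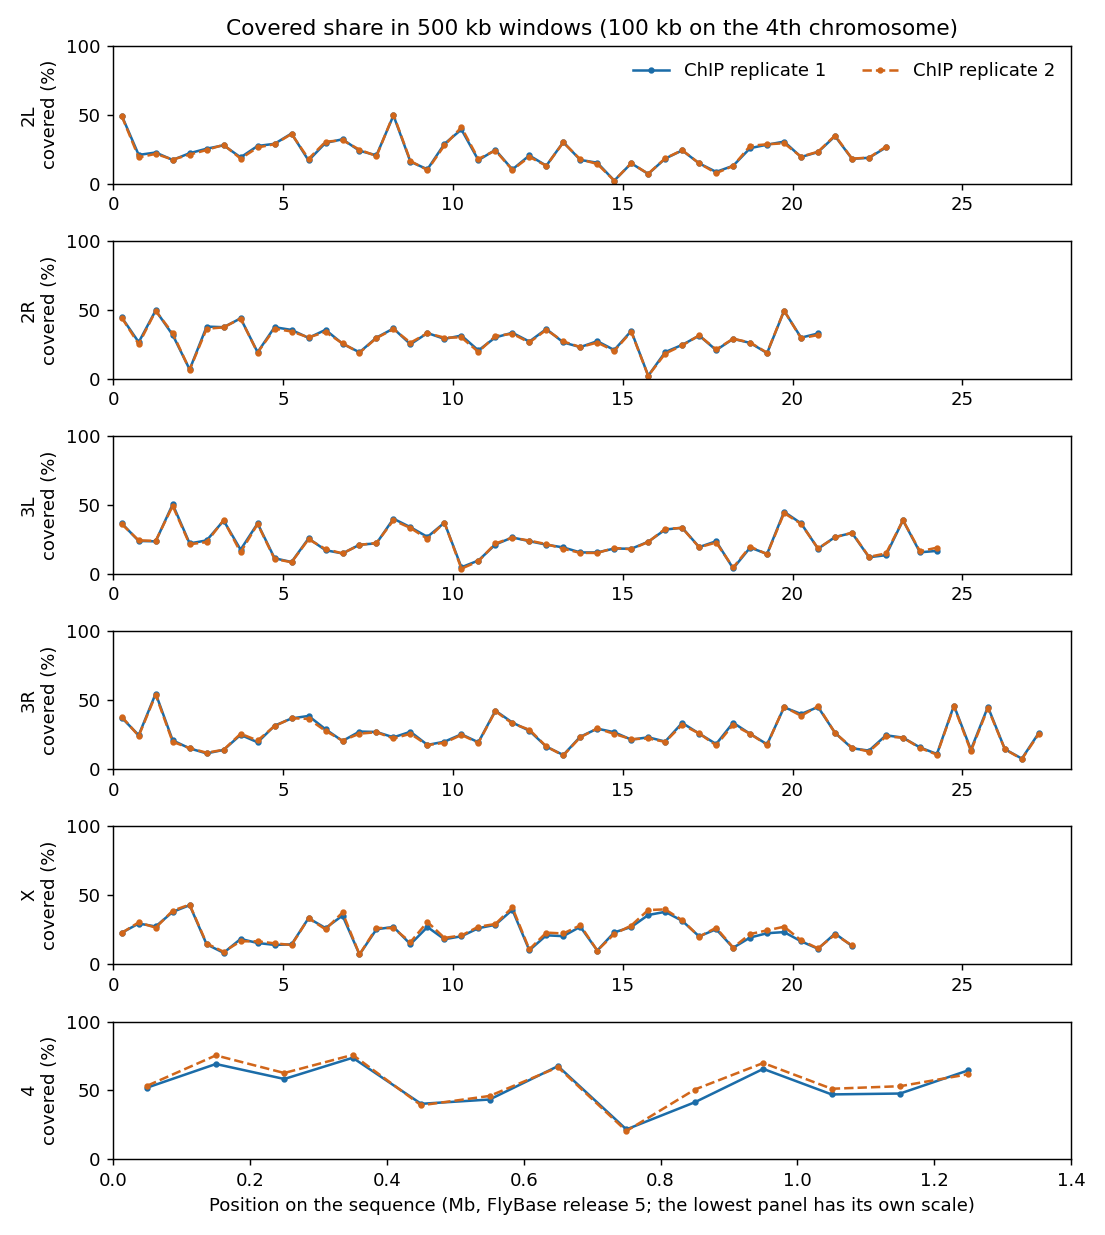
Covered share (y axis, percent) in consecutive windows of 500 kb along the 5 large arms and of 100 kb along the 4th chromosome (x axis, position in Mb); solid lines are ChIP replicate 1 and dashed lines ChIP replicate 2. The lines of the replicates nearly coincide on the large arms, where no window differed by more than 3.91 percentage points.

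The longest and highest-scoring regions lay in a few places, several of them in the first 1.5 Mb of 2R, the end of that arm next to the centromere. The longest region of the replicate-set list was 2R 273360 to 358558, 85.2 kb with a score of 2.87. It was 1 region in replicate 1 and 2 in replicate 2. Next were 3LHet 2409788 to 2494855 at 85.1 kb, 3LHet 1303846 to 1373612 at 69.8 kb, 2L 4478011 to 4538228 at 60.2 kb and 2R 6365948 to 6422262 at 56.3 kb. Replicate regions covered at least 97.0% of each of these in both lists. The highest score, 3.40, belonged to 2R 1109359 to 1117146, which scored 3.48 in replicate 1 and 3.31 in replicate 2. It was followed by 2RHet 2806617 to 2823665 at 3.32, 2R 1119281 to 1138639 at 3.25, 2L 182836 to 201558 at 3.16 and 2R 222004 to 268005 at 3.11, each matched by a single region in both replicates.

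The longest regions of the other sequences were shorter than these. They measured 43.8 kb on 3R (24517011 to 24560778), 43.0 kb on X (11829707 to 11872743), 40.7 kb on 3L (23226144 to 23266862) and 25.1 kb on the 4th chromosome (300969 to 326080). On the heterochromatin sequences they measured 52.2 kb on 2RHet (3127420 to 3179570), 48.5 kb on 3RHet (1934715 to 1983189), 16.7 kb on 2LHet (15760 to 32414) and 14.7 kb on XHet (60206 to 74917). On U the longest was 15.4 kb (1350234 to 1365617). Each was overlapped in both replicates.

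**Figure D4:**
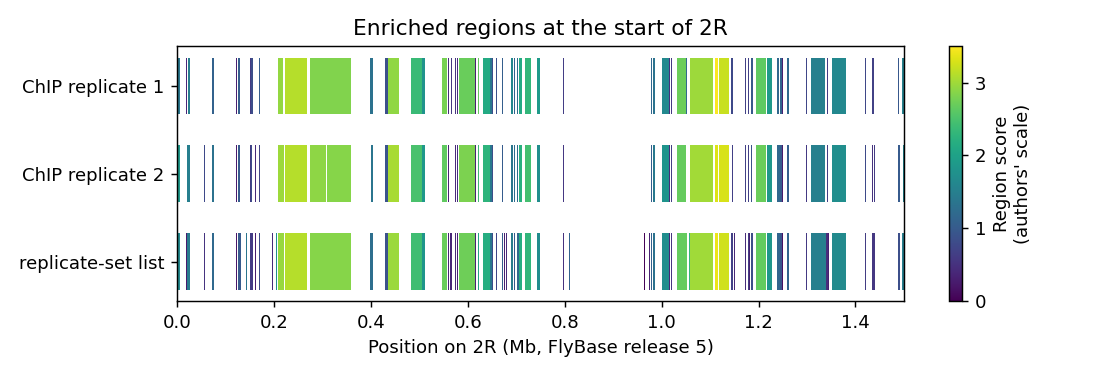
Enriched regions on the first 1.5 Mb of 2R (x axis, position in Mb, FlyBase release 5) in ChIP replicate 1, ChIP replicate 2 and the replicate-set list, coloured by the authors' score. The 85.2 kb region of the replicate-set list at 273360 to 358558 is matched by 1 region in replicate 1 and by 2 in replicate 2, and the region with the highest score, 3.40, at 1109359 to 1117146 by 1 in each.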

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

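The replicate-set list named 7 regions as depleted rather than enriched, and none of the comparisons above used them. They were 1345 to 1840 bp long, with scores between -0.061 and -0.0058. Each replicate list named 1 depleted region, on the 4th chromosome in replicate 1 and on 2R in replicate 2, and the latter overlapped the set's region at 2R 927535 to 929374. Of the 7, 5 overlapped a region named as enriched in a replicate, by 93.8% of their length or more, and the one at 3L 15801913 to 15803388 did so in both replicates. No explanation was tested for this contradiction between lists. The scores of the 7 regions lay close to 0, and no biological explanation was tested. The depleted regions named here by position were chosen after their values were seen.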

How the results depend on the processing

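Of 35 alternatives over 10 results, 19 left the value within 1.5 times for a count of regions, within 1 SD of the replicates for a value without a test, or on its side of the threshold for a test, 16 moved it further and 0 reversed it. Of the 19, 6 left out a replicate and say nothing about stability, since with 2 replicates each lies within 1 SD of their mean by construction. The comparison of 1 shortened list with the whole other list and the use of bases covered in both replicates were chosen after seeing the data. No paired analysis was possible because no input values were analysed here and the ChIP samples form a single group. The overlap of the replicate lists passed its test, whose outcome was likely in advance, under all 3 of its alternatives. The Jaccard index was 0.870 to 0.905 in these, and the Spearman rho of scores was 0.965 with the stricter pairing. Joining regions closer than 1 kb left 4471, 4358 and 4390 regions in the replicate 1, replicate 2 and replicate-set lists, so that the replicate-set list no longer had the most. Keeping the higher-scoring 50% left, by construction, 3081, 3039 and 3206 regions in the same order. It lowered the covered share of the 5 large arms to 17.8% and the shared regions to 93.7%, and it moved the ratios to the autosomal arms to 0.972 for X, whose regions rank higher on the score used as the filter, 2.04 for the 4th chromosome and 0.748 for heterochromatin. Shortening only 1 list in this way gave 99.6% shared. Requiring 50% of a region's length gave 94.6% shared, and the 5 large arms alone gave 95.6%. The covered share of the 5 large arms was 25.1% with regions closer than 1 kb joined and 27.2% in the replicate-set list, which also gave ratios of 0.951 for X and 0.665 for heterochromatin. Measuring sequences from their first to their last region moved heterochromatin to 0.713. Apart from the region counts, the cause was not tested. Leaving out each replicate leaves 1 list, a value with no test, and gave ratios of 0.897 and 0.936 for X, 2.07 and 2.19 for the 4th chromosome, and 0.621 and 0.638 for heterochromatin. The 9 alternatives on gene annotation were not run. With depth unknown, a region missing from 1 list may lie below its threshold rather than be absent, and the 99.6% shared among the higher-scoring regions limits this mostly to lower-scoring ones.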

Other observations

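All tests in this part were chosen after the results were seen, and for the scores of X regions and the regions of the replicate-set list several tests were tried in turn. Between enriched regions the large arms held long stretches with no enriched region in any of the 3 lists. There were 191 such stretches of 100 kb or longer on the 5 large arms, 29.8 Mb in total. The longest was 3L 22302563 to 22708830 at 406 kb, followed by 2R 2144751 to 2501046 at 356 kb, 3R 12480650 to 12804255 at 324 kb and X 7237587 to 7553500 at 316 kb, each chosen after its values were seen. Such stretches took up 29.5% of 2L, 27.9% of X, 26.7% of 3L, 24.0% of 3R and 16.4% of 2R. The 4th chromosome had none, and its longest stretch was 43.6 kb. Whether these stretches hold silent genes, few genes or gaps in the sequence was not examined.

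Covered share near the arm ends differed from arm to arm. The 2 Mb next to the centromere were covered over 38.0% ± 0.12 (SD, n = 2) on 2R and 34.1% ± 0.31 (SD, n = 2) on 3R, 1.32 and 1.35 times the share of the whole arm. The ratio was 1.09 on 2L, 0.942 on 3L and 0.568 on X. Over the 5 large arms together these windows had 26.3% against 24.4% elsewhere (two-sided permutation p by rotation, adjusted over 2 tests, 0.44). The 2 Mb next to the telomere had 28.1% against 24.2% (adjusted permutation p = 0.24). There the ratio to the whole arm ranged from 0.729 on 3R to 1.44 on 3L. Neither test passed, so a common trend toward either end was neither shown nor excluded.

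Within 20 length classes, X regions scored 0.143 ± 0.027 (SD, n = 2) above autosomal ones. The exact rotation p was 0.0014 in each replicate (exact rotation p adjusted over the 5 arms, 0.007). X regions had median lengths of 3208 bp in replicate 1 and 3468 bp in replicate 2. The medians of the autosomal arms were longer, 3642 to 3847 bp. Longer regions carried higher scores (Spearman rho 0.80 in each replicate), so length alone would lower X scores. These values argue against region length as the cause. Each autosomal arm was compared only with the other autosomal arms, without X (4661 regions in replicate 1). Smaller differences on 3L (0.033, adjusted exact rotation p = 0.017) and 2L (-0.031, adjusted exact rotation p = 0.042) also passed in replicate 1. They did not pass in replicate 2 (adjusted exact rotation p = 0.14 and 0.36). The rotation test cannot decide whether high scores fell on X by chance. X held 1131 of the 5792 regions compared in replicate 1, so its rotated positions overlap one another heavily. A threshold that only higher-scoring X regions pass would shrink the difference among long regions, and an offset of X as a whole between ChIP and input would leave it. At 8 kb or longer the difference was 0.142 (bootstrap 95% interval 0.067 to 0.217), with an unadjusted exact rotation p of 0.027 in replicate 1 and 0.041 in replicate 2. In the replicate-set list it was 0.108 (unadjusted exact rotation p = 0.094). At 15 kb or longer it was 0.012 (-0.13 to 0.16, from 27 and 29 X regions). There it was -0.017 in replicate 1, 0.042 in replicate 2 and 0.068 in the replicate-set list (40 X regions). The bootstrap intervals treat regions as independent, which they are not, so they do not measure the spread between chromosomes. Tests set aside were the covered-share ratio of 0.916, since the share X would have without an offset is unknown, and dropping all regions under the 5th percentile of X regions of their length, which gave 0.074 but takes its limit from X and removed 5.70% of X and 26.9% of autosomal regions. The threshold and the offset cannot be told apart, because these values point in different ways, their intervals are wide and the lists hold no background values. A higher level of the mark on X is a hypothesis that stays open and untested.

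Some regions seen in 1 replicate had high scores and lay on heterochromatin or unplaced sequence, such as the highest-scoring region of replicate 2, 2RHet 1534827 to 1536174, chosen after its value was seen. On these sequences 7.02% of regions lacked a partner in replicate 1 and 13.4% in replicate 2, against 4.42% and 4.38% on the large arms (Fisher's exact p, adjusted over 6 tests, 0.095 and 1.2e-07; raw p 0.079 and 4e-08). In the higher-scoring 50% of each list the shares were 2.19% against 0.104% in replicate 1 (3 of 137 and 3 of 2891 regions, Fisher's exact raw p = 0.0016, adjusted 0.0024) and 8.45% against 0.176% in replicate 2 (12 of 142 and 5 of 2839, raw p = 4.4e-13, adjusted 2.6e-12), and among regions under 2 kb they were 26.3% against 20.8% in replicate 1 (raw and adjusted p = 0.32) and 50% against 23.3% in replicate 2 (raw p = 2.6e-05, adjusted 5.2e-05). In replicate 2 these values argue against a low score alone, or a length under 2 kb alone, as the whole cause. No test held length and score together, and 2RHet 1534827 to 1536174 is 1348 bp long against a shortest replicate 2 region of 1301 bp. Regions near a length limit therefore stay open. In replicate 1, where the 2.19% rests on 3 regions and the short regions did not pass, short regions near a threshold stay open. Fisher's test treats regions as independent, which they are not. Reads shared among repeat copies may be the source of the 10.2% of regions there without a partner, which stays open because the lists hold no alignments, and no biological explanation was tested.

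Of the 674 regions of the replicate-set list found in neither replicate, 349 were shorter than 1301 bp, the shortest region of either replicate. Another 23 regions under that length overlapped a replicate region. The replicate-set list reached down to 1001 bp, and no replicate list held a region under 1301 bp. That difference in shortest length nearly fixed this split, so the counts test no cause. The other 325 were not shorter, but only 24 of them exceeded 1301 bp by more than the 90th percentiles of the start and end shifts between replicates (426 and 396 bp) together, so a minimum length could still account for many of them and stays open. Weaker regions that pass only with the replicates combined would score lower than regions found in both replicates at the same length, but the 157 that could be matched, all of 1500 bp or longer, scored 0.124 higher (bootstrap interval 0.072 to 0.179, permutation p = 1e-05, the smallest that 100000 permutations can give), and 0.082 higher on the large arms alone. Without matching on length the medians ran the other way, 0.348 for these 157 regions and 0.539 for the 1463 compared regions found in both. The bootstrap interval and the permutation p treat regions as independent, which they are not. Earlier tests, of whether most of the 325 scored under the list's median and of whether any was not shorter, were set aside because length and boundary shifts nearly fixed their outcome. What produced these regions stays open, and no biological explanation was tested.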
